A study of Drosophila melanogaster with 3 samples.

How the data were processed

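The protein studied was the product of the Drosophila melanogaster gene CG3838, now called brickwall (brwl). Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole embryos of mixed sex, aged 0 to 24 h, from a stable transgenic line carrying CG3838 joined at its C-terminal end to green fluorescent protein (GFP). Per the labels, the antibody recognised GFP, although the antibody field itself names CG3838. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The samples form 1 group of 3 biological replicates, numbered in the labels. There was no second group, and the control library was not analysed here.

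The deposited data are peak lists. Per the README files deposited with the samples, peaks and background regions were called by the authors on the alignments of each replicate against 1 shared control file for each genome build, and again on the alignments of the 3 replicates pooled. A further list holds the peaks that passed the authors' optimal threshold of the irreproducible discovery rate (IDR), a filter on agreement between replicates. The lists exist for the older build dm3 and for dm6. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. Each region carries a signal value as the authors' caller gave it, a −log10 q value deposited in its own column, and a summit position. The signal is the authors' own value for the region, on a scale that is not described, and was used here only to rank and describe regions within a list. The deposited −log10 q value was not used to rank, because 1697 of the 2239 thresholded dm6 regions share its highest value of 3.53.

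A check of the lists found that the thresholded list holds exactly the 2239 strongest of the 15592 pooled regions on dm6, and the 1878 strongest of 11691 on dm3. The lists of replicates 1 and 2 on dm6 both stop at 30000 regions and that of replicate 3 holds 21147. The lists give no read counts, so the depth of each replicate is unknown and no interval that needs it is given. Of the thresholded regions, 2059 have the same width of 424 bp, and the 2239 regions fall in 2234 distinct intervals because some intervals hold more than 1 summit. In the text below, a peak is 1 summit of the thresholded dm6 list.

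Peaks were annotated with the Ensembl gene set of release 115, whose assembly is the same as dm6, and with the dm6 sequence. No dm3 sequence or annotation was used here. A promoter peak had its summit within 500 bp of an annotated transcription start site (TSS) of any gene. Other summits were placed in the first class that held them among exons by type, introns and intergenic sequence, and the expected share of each class was its share of the length of the arms 2L, 2R, 3L, 3R, 4, X and Y. Shares of peaks were compared with these by exact binomial tests, two-sided. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

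To compare replicates, the strongest N regions of each replicate list were taken, N being the 2239 of the thresholded list, and regions overlapping by at least 1 bp counted as shared. Mitochondrial regions of replicate 3 stayed in its list for this and were left out where its regions were annotated. The overlap expected by chance came from 100 random placements within the chromosomes. Signal at promoter and other peaks was compared by a permutation test of the mean log2 signal with 100000 resamples. A gene counted as having a peak when a summit lay within 500 bp of one of its TSSs. Shares were compared by Fisher's exact test, two-sided, for genes with divergent promoters, which are protein-coding genes whose TSS lies within 1000 bp of that of a gene transcribed away on the other strand. The same test was applied to 26 gene lists against all 13968 protein-coding genes, or against the 4309 other genes for tRNA genes. Of 462 symbols written by name, 30 were matched by a synonym and 13 were not matched. For 29 consensus motifs, windows of 201 bp centred on summits were compared with windows of that size centred 1000 bp to each side that overlapped no thresholded peak, both strands being searched. Peaks and genes are not independent replicates, neighbouring genes can share a promoter and its peak, and these p-values describe the list rather than the spread between replicates. For that reason values from each replicate's own list are given beside many of them.

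The comparisons, tests, gene lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. Named are the tagged gene, the nearest genes to the 15 peaks of highest signal found among the strongest N regions of every replicate, up to 4 members of each gene list past the threshold and up to 2 of each other list by signal of their promoter peak, the motifs past the threshold, and the 5 most enriched 6-mers. The alternatives covered the overlap rule, list lengths, promoter windows of 250 and 1000 bp, the TSS set, stricter peak sets (the stronger 50% and the strongest 500), each replicate's own list, the dm3 lists, other backgrounds, and the peaks supported by both remaining replicates when 1 was left out. A pair of alternatives was added after seeing the data.

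The tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. They were tested on simulated data. In 20 sets of 2239 randomly placed peaks, 1 of 520 gene list tests and 0 of 580 motif tests passed the threshold, and the promoter share passed in 1 of 20. All 100 of 100 planted lists, each of 40 genes of which 40% were given a peak, were called, and a motif planted in 5% of windows was called in 20 of 20 sets. A planted log2 signal difference of 0.15 was called in 5 of 5 sets. The random peaks were spread evenly over the arms rather than gathered at promoters, so fewer genes had a peak than in the data. Their motif windows were compared with windows closer than the 1000 bp flanks. These runs thus do not show how often contrasts weaker than the planted ones are called, nor how base composition of the flanks affects motif calls.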

Results

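Binding of the GFP-tagged CG3838 (brwl) protein was mapped in 3 biological replicates of whole mixed-sex embryos covering 0 to 24 h of development. The thresholded list made from them holds 2239 peaks on dm6, with signal values from 103.5 to 1796 and a median of 148.5. The depth of the replicates is unknown, since the lists carry no read counts. As there is 1 group, the comparisons are between replicates, and between parts of the genome with and without peaks. No sample of a line without the tagged protein was used, and chromatin accessibility was not measured. Signal from accessible chromatin or from the antibody thus cannot be told apart from binding of the protein.

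The strongest peak in the genome lay at the tagged gene itself. Gene brwl (FBgn0032130) occupies 2L from 9568890 to 9573572 on the forward strand of dm6, and 1 interval from 9567326 to 9569610 at its 5' end held 4 of the 15 strongest peaks. Their summits, at 9568433, 9567705, 9568951 and 9568669, had signals of 1796, 1633, 1448 and 881, which ranked 1, 3, 4 and 14. The summit at 9568951 lay 61 bp downstream of the first annotated brwl TSS, in the first exon, and that at 9568433 lay within lncRNA:CR44149, a non-coding gene on the opposite strand. The summit at 9567705 was intergenic, and its nearest TSS was that of junctophilin (jp), the gene of a membrane junction protein. Inside the gene, weaker peaks followed at 9569803, with a signal of 373, and at 9570808 in the 5' untranslated region, with a signal of 534. In the replicates' own lists the interval was the strongest region of replicate 1 (signal 694.8) and of replicate 2 (859.8), and ranked 21 in replicate 3 (424.3), below 20 regions of which 19 were mitochondrial. Weak pooled regions under the threshold were also frequent there, with 13 within 10 kb of brwl, compared with a median of 3 around random protein-coding genes.

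**Figure D1:**
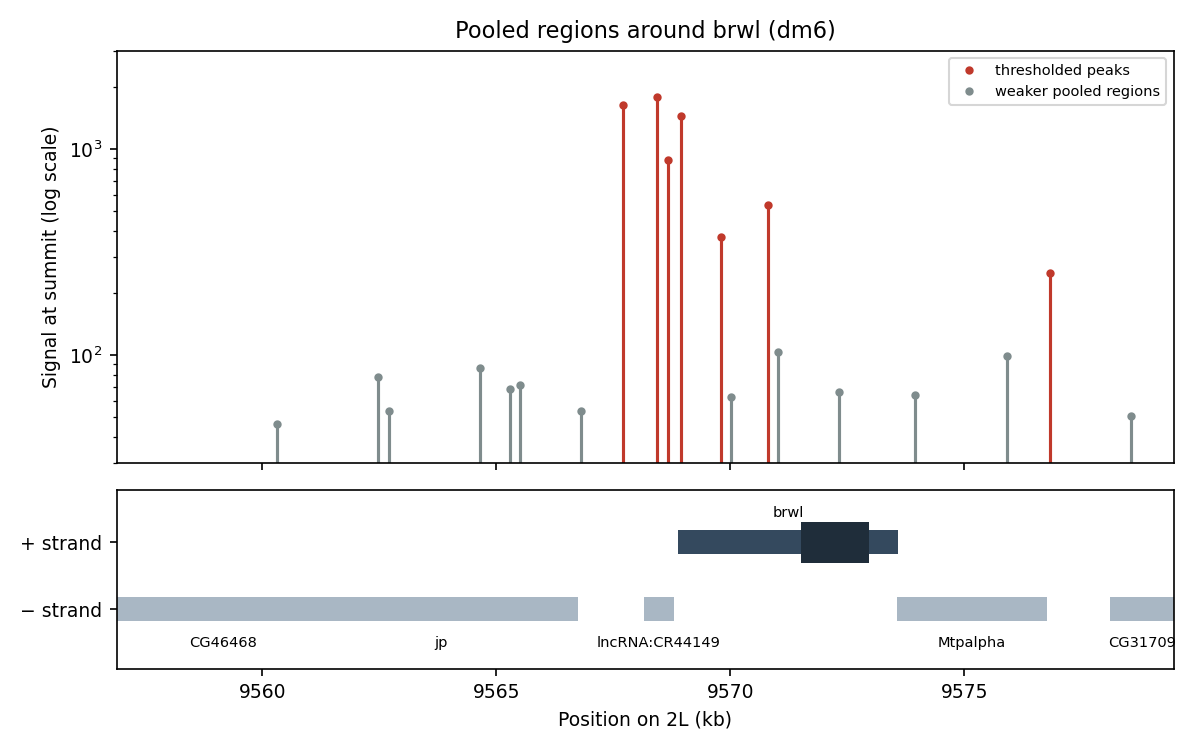
Signal of each pooled region at its summit (vertical axis, log scale, the authors' units) against position on 2L in kb, around brwl on dm6. Red stems are thresholded peaks and grey stems weaker pooled regions, with genes by strand below and the coding span of brwl as the taller dark box. The red stems of highest signal, up to 1796, stand at the 5' end of brwl, while the region within its coding span reaches 66.0.

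The other peaks of highest signal lay near genes of varied function. The peak second in rank, with a signal of 1676, was in an intron of COX7AL2, a gene of the cytochrome c oxidase 7A family, on 2L at 2197264. Promoter peaks followed at CG14100 (1333), at Rlip (1310), which encodes a Ral-binding protein, at the non-coding gene lncRNA:CR31840 (1258), and at tou (1184), which encodes a chromatin-remodelling factor. Further promoter peaks were those of Ugalt (1182), a UDP-galactose transporter, px (1060), a wing vein gene, Sec10 (1032), a subunit of the exocyst, and Art3 (875), an arginine methyltransferase gene. Summits in introns had as their nearest TSS that of cbt (1292), a zinc finger transcription factor gene, and that of CG11050 (1111). The rule for naming required each of these peaks to be among the strongest 2239 regions of every replicate.

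The first comparison asked how far the replicates found the same regions. A thresholded peak was found among the strongest 2239 regions of a replicate in 79.9% ± 3.88 of cases (SD, n = 3), with 80.5%, 83.5% and 75.8% in replicates 1, 2 and 3. Randomly placed lists gave 1.37% to 1.42%. All 3 replicates held 1222 of the peaks (54.6%), and 0.625% were in none. Pairs of replicates shared 67.0% ± 4.52 of their strongest regions (SD over 3 pairs), with 72.2% for replicates 1 and 2, 64.9% for 1 and 3 and 64.0% for 2 and 3. Across the thresholded peaks, which are not independent of each other, Spearman's rho between the replicates' signals was 0.679, 0.536 and 0.486 for the same pairs, a mean of 0.567 ± 0.100. The thresholded list was itself made from these replicates and they share 1 control file, so the overlaps are not independent of it.

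Peaks were concentrated at promoters, and coding sequence outside promoter windows held few of them. Summits within 500 bp of a TSS numbered 1272 of 2239 (56.8%, interval 54.7% to 58.9%), against 13.3% of the arms' length, a ratio of 4.28 (exact binomial test, −log10 p of 512). The replicates' own strongest regions gave 55.4%, 54.0% and 60.1%, a mean of 56.5% ± 3.21 (SD, n = 3), so that the excess over 13.3% was far larger than the spread between replicates. Coding exons held 9 summits (0.402%), against 13.4% of the length (exact p = 4.69e-123), and 3' untranslated regions held 18 (0.804%), against 4.31% (p = 6.59e-23). Introns held 30.5% of summits, against 39.1% (exact p = 2.53e-17), and intergenic sequence 9.51%, against 28.3% (p = 4.29e-106). The shares in 5' untranslated regions, at 1.03% against 0.758% (exact p = 0.143), and in non-coding exons, at 0.938% against 0.821% (p = 0.483), did not differ from expectation by the same test. A promoter summit is placed in no other class, so the promoter excess lowers the shares of the other classes by construction. Of the 967 summits outside promoter windows, 683 were in introns, and these summits were not tested against the length outside promoter windows.

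**Figure D2:**
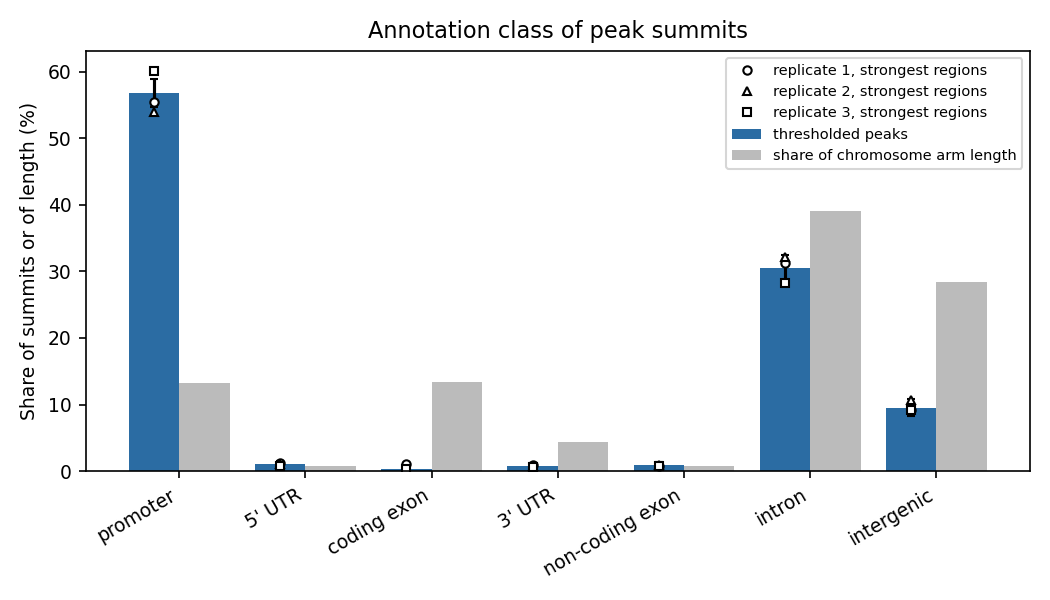
Share of thresholded summits in each annotation class (blue bars, %, with exact 95% intervals) beside the share of chromosome arm length in that class (grey bars, %). Symbols give the share in the strongest regions of each replicate. The promoter bar stands at 56.8% against 13.3%, and the coding exon bar at 0.402% against 13.4%.

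Promoter summits lay mostly on the upstream side of the TSS. Their median position was -102 bp relative to the nearest TSS, with quartiles at -187 and -19.8 bp, and 79.0% of them were upstream. A summit between the TSSs of a divergent pair is upstream of both, which raises this share by construction, and no split by divergent promoters was made. Stronger peaks were more often at promoters, with 66% of the strongest 100 and 64% of the strongest 500, while 33.6% of the 13353 weaker pooled regions had a promoter summit. Within the thresholded list, the mean log2 signal was 7.43 at the 1272 promoter peaks and 7.33 at the 967 others, a difference of 0.10 (two-sided permutation test, p = 0.00024). The medians were 152.6 and 142.7. In the replicates' own lists the difference was 0.14, 0.07 and 0.13, higher at promoters in 3 of 3.

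Genes with divergent promoters carried peaks far more often than the rest. Of 5052 protein-coding genes with a TSS within 1000 bp of that of a gene transcribed away from it, 1078 had a promoter peak (21.3%), compared with 547 of 8916 others (6.14%), an odds ratio of 4.15 (Fisher's exact test, p = 1.19e-152). RpS27, a small ribosomal subunit gene, and Nup37, a nucleoporin gene, shared 1 such peak on 3R at 25247534 with a signal of 523.6. Art3 and the mitochondrial ribosomal protein gene mRpS10 shared another at 15229504 on 3R. The replicates' lists gave odds ratios of 3.81, 3.67 and 4.79. One shared peak counts for both genes of a pair, which raises the share of divergent genes by construction.

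The share of peaks on the X chromosome did not differ from its share of the length by the test used. The X carried 351 peaks (15.7%, interval 14.2% to 17.2%), against 17.1% of the assembled length (exact binomial test, adjusted p = 0.127), a ratio of 0.916. Against its share of protein-coding genes the ratio was 0.997 (exact binomial test, p = 0.977). In the list of replicate 3 alone the ratio was 0.863 with an exact p = 0.00304, before adjustment for the other arms. The small chromosome 4 held 8 peaks, 0.357% against 0.980% of the length (exact binomial test, adjusted p = 0.00409). Its share of protein-coding genes, 0.573%, lay within the interval on its share of peaks, 0.154% to 0.703%. No region of any list lay on the Y, where the mapping of repeats was not examined.

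Ribosomal protein genes stood out among the 26 gene lists. In all, 1625 of 13968 protein-coding genes (11.6%) had a promoter peak, compared with 44 of the 93 genes of cytoplasmic ribosomal proteins (47.3%, interval 36.9% to 57.9%, Fisher's exact test, adjusted p = 2.7e-16). The replicates' lists gave 45, 47 and 27 of the 93, above background by the same exact test in each (adjusted p = 1.78e-18, 2.46e-20 and 0.000113). The strongest promoter peaks of the list were those of RpS27 (signal 523.6), RpL7 (371.7), RpL19 (315.4) and RpL34b (288.2). The median signal of its members with a peak was 162.8, close to the 156.3 of all protein-coding genes with a peak. Genes of the large subunit had peaks more often, in 31 of 54 (57.4%), than those of the small subunit, in 13 of 39 (33.3%, Fisher's exact test, p = 0.0347), a split made after seeing the data. Because 56 of the 93 genes have divergent promoters, the count was also set, after seeing the data, against draws of genes with the same number of divergent promoters, which gave an expected 14.2 with a peak (permutation test, p = 2e-05, the smallest that it can give).

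Genes of the Notch pathway and the E(spl) complex, which act in cell fate choice, formed the second list above background, with 8 of 25 (32%, adjusted p = 0.0300 by Fisher's exact test). The strongest of their promoter peaks were at numb (203.6), whose product inhibits Notch, E(spl)m3-HLH (169.7), a Notch target encoding a basic helix-loop-helix protein, aph-1 (163.3), a gamma-secretase subunit, and bib (145.4), which encodes a membrane channel-like protein. The symbol Dl (Delta) matched no single gene and is missing from the 25, which include Kaz-m1, matched by a synonym. The replicates' lists held 7, 7 and 8 of the 25. This call depended on the setting, with an adjusted p of 0.483 for a 250 bp window and between 0.0187 and 1 over all alternatives. When the peaks had to be supported by both remaining replicates, adjusted p was 0.0523, 0.0544 and 0.0608 without replicates 1, 2 and 3, on fewer peaks, while the ratio to background was 3.13, 3.10 and 3.03, compared with 2.75 in the main list.

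Genes of odorant, gustatory and ionotropic receptors and of cuticle proteins had no promoter peak. None of 179 odorant and gustatory receptor genes (Fisher's exact test, adjusted p = 5.15e-09) and none of 123 cuticle protein genes (adjusted p = 4.59e-06) had one, and the same held in all 3 replicate lists. Among the genes with a region of any strength in any dm6 list, 0 of 33 receptor genes and 0 of 47 cuticle genes had a thresholded peak (same exact test, adjusted p = 0.0197 and 0.00208). The 111 replication-dependent histone genes also had none (exact test, adjusted p = 1.12e-05), but they are near-identical tandem copies and no list had any region at their promoters, so whether reads could be placed there is uncertain. With the strongest 500 peaks alone, which leave 3.05% of protein-coding genes with a peak, these 3 calls were lost (same exact test, adjusted p = 0.0927 for receptors and 0.293 for both other lists). With a 1000 bp window, 1 cuticle gene had a peak.

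**Figure D3:**
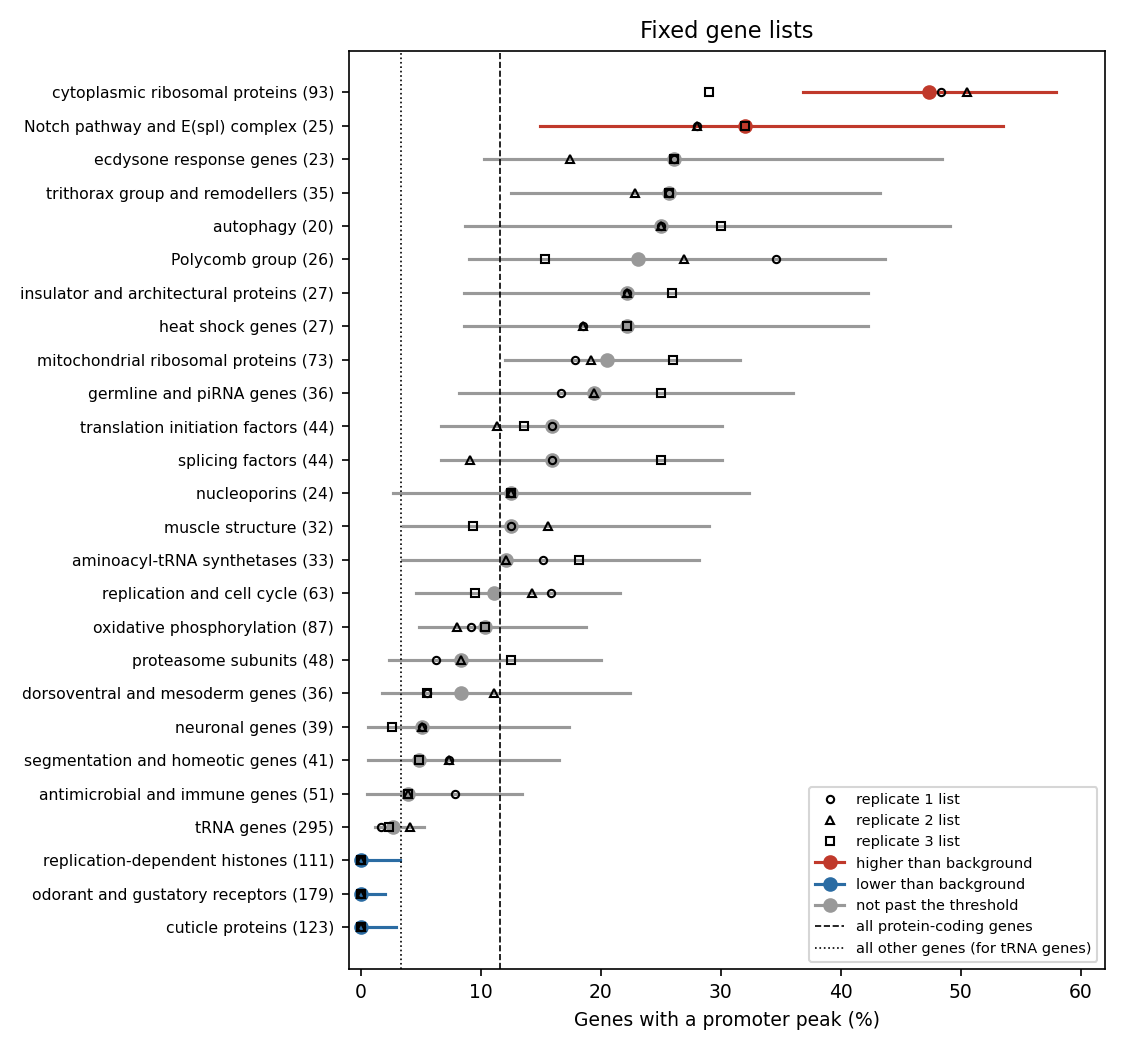
Percent of the genes of each fixed list (rows, number of genes in brackets) with a thresholded promoter peak, as filled circles with exact 95% intervals, and open symbols for each replicate's own strongest regions. The dashed line marks all protein-coding genes at 11.6% and the dotted line the other genes at 3.37%. Cytoplasmic ribosomal proteins stand at 47.3% and 3 lists at 0.

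The remaining 21 lists did not pass the threshold, and their values are given without direction. In protein synthesis and energy supply, 15 of 73 mitochondrial ribosomal protein genes had a peak (20.5%, exact test, adjusted p = 0.0967), among them mRpS10 (875.4) and mRpL41 (792.4). The counts were 7 of 44 for translation initiation factors, with eIF6 (480.9) and eIF4EHP (365.3), 4 of 33 for aminoacyl-tRNA synthetases, with IleRS (214.9) and GluProRS (210.8), and 9 of 87 for oxidative phosphorylation, with ND-ASHI (245.6) and ND-24 (206.0). Proteasome subunits had 4 of 48, with Rpn3 (194.9) and Rpn5 (163.3). Of 295 tRNA genes, 8 had a peak (2.71%, against 3.37% of all non-protein-coding genes), including tRNA:Tyr-GTA-1-8 (357.8) and tRNA:Phe-GAA-1-2 (168.7).

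Among genes of chromatin and the nucleus, the trithorax group and remodellers had 9 of 35 (25.7%, exact test, adjusted p = 0.0704), with Ino80 (272.4) and brm (213.2), the ATPase of the Brahma complex. The Polycomb group had 6 of 26 (exact test, adjusted p = 0.242), with ph-p (712.5) and E(z) (216.7), a histone methyltransferase. Insulator and architectural proteins had 6 of 27, with Chro (867.4) and Cp190 (347.0). Nucleoporins had 3 of 24, with Nup37 (523.6) and Nup98-96 (184.1), splicing factors 7 of 44, with SF2 (165.3) and U2af50 (165.0), and replication and cell cycle genes 7 of 63, with Cdk1 (170.1) and SMC2 (146.4).

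Developmental, signalling and stress genes made up the rest. Segmentation and homeotic genes had 2 of 41, hth (224.4) and bcd (144.6), and dorsoventral and mesoderm genes 3 of 36, with ush (166.1) and SoxN (137.1). Neuronal genes had 2 of 39, elav (429.0) and Syx1A (175.1), and muscle structure genes 4 of 32, with Zasp66 (244.1) and Msp300 (218.0). Germline and piRNA genes had 7 of 36, with papi (239.9) and orb (164.6), ecdysone response genes 6 of 23, with the nuclear receptor genes Hr39 (502.4) and Eip78C (317.1), and autophagy genes 5 of 20, with Atg2 (177.2) and Atg17 (176.6). Heat shock genes had 6 of 27, with Hsp27 (269.0) and Hsc70-5 (190.7), and antimicrobial and immune genes 2 of 51, imd (473.9) and Myd88 (120.6).

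The DNA replication-related element (DRE), a promoter element of housekeeping genes, had the highest odds ratio at summits against flanking windows. Its core TATCGATA was found in 3.89% of the 2239 summit windows and in 0.423% of 4254 flanking windows, an odds ratio of 9.51 (Fisher's exact test, adjusted p = 3.13e-23), and 8.66, 8.38 and 13.6 in the replicates' lists. Motif 1, another core promoter element, was found in 2.23% against 0.494% (odds ratio 4.60, exact test, adjusted p = 6.23e-09), and the E-box variant CAGCTGWT in 4.91% against 2.07% (odds ratio 2.45, adjusted p = 7.85e-09). The other motifs above background were the TATA box (13.4% against 7.92%), Motif 6 (13.6% against 10.1%), the homeodomain core TAATTA (15.3% against 11.6%) and the GATA site (37.7% against 31.0%), by the same exact test with adjusted p = 1.11e-10, 0.000182, 0.000119 and 4.41e-07. Stat92E sites (4.69% against 6.25%, exact test, adjusted p = 0.0311) and Ttk sites (0.491% against 1.18%, adjusted p = 0.0231) were rarer at summits, and the other 20 of 29 motifs did not pass.

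**Figure D4:**
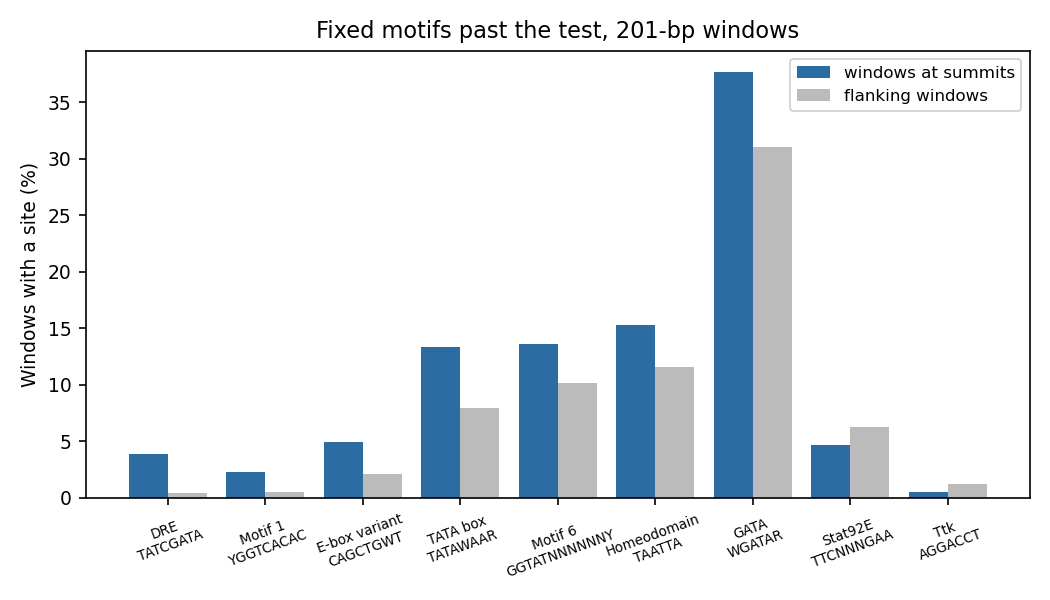
Percent of 201-bp windows with a site for the 9 fixed motifs past the threshold, at summits (blue) and in flanking windows 1000 bp away (grey), ordered by odds ratio. DRE stands at 3.89% against 0.423% and GATA at 37.7% against 31.0%.

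Base composition differed between these windows, with GC content 6.15 percentage points lower at summits than the 43.1% of flanks, and the 5 most enriched 6-mers of 2080 were the AT-rich words AAATAT (49.0% against 26.8%), AAAATA, TTAAAA, TAAATA and AAATAA. Motif 1 and the E-box variant lost their calls only with the strongest 500 peaks, where fewer windows were tested. Of the motifs above background, DRE alone kept its call under every alternative, but with a smaller margin in some. Between promoters with and without a peak its odds ratio was 1.28 (9.42% against 7.49%, exact test, adjusted p = 0.0217), below those of the E-box variant (2.11), CAGCTG (1.72), GAGA (1.61), Motif 1 (1.58) and CACGTG (1.47), and against dinucleotide-shuffled windows it was 9.01, below that of Motif 1 (2.23% against 0.134%). Against shuffled windows the odds ratios of the homeodomain core and GATA fell to 0.990 and 0.959, between promoters with and without a peak that of the homeodomain core was 1.07 (exact test, adjusted p = 0.625), and in the list of replicate 1 alone its call was lost (odds ratio 1.19, adjusted p = 0.0588). Between promoters with and without a peak TATA and GATA were rarer in the former, with odds ratios of 0.537 and 0.843. The promoter contrasts used windows centred on a TSS, the nearest to a summit with a peak and the 5'-most without one. They are thus not centred on promoter summits, whose median position was -102 bp, and the unlike choice of TSS may affect their odds ratios. Motif 6 lost its call against shuffled windows (exact test, adjusted p = 0.362), between promoters (0.851), with the stronger 50% (0.119) and strongest 500 peaks (0.294), and without replicates 1 (0.0813) and 3 (0.0534), where its odds ratio of 1.39 became 1.26 and 1.27 on fewer windows. Stat92E lost its call under every alternative, with adjusted p from 0.0573 to 0.614, though its odds ratio of 0.738 moved only to between 0.742 and 0.773 without each replicate. Ttk kept its call in replicates 1 and 3 alone and lost it under all other alternatives. Its odds ratio of 0.415 stayed below 1, between 0.416 and 0.785 over all alternatives and between 0.489 and 0.581 without each replicate.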

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

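All tests of explanations in this part were chosen after the results were seen. Regions on the mitochondrial genome appeared in the lists of replicate 3 alone. Its dm6 list held 25 mitochondrial regions, 19 of them among its strongest 20, with signals from 44.5 to 2812, compared with a highest signal of 440 on its chromosome arms. Its dm3 list held 6, with a highest signal of 209.5. The dm6 lists of replicates 1 and 2 held 0, but so did the pooled list, which was made from all 3 replicates. A 0 may thus come from how a list was made and does not exclude binding of the tagged protein to mitochondrial DNA. The regions fell in 14 of the 1-kb bins, between positions 1 and 14879 of the 19524 bp sequence, so more mitochondrial DNA in that library than in its control may be a source of them. The highest mitochondrial signal was 13.4 times higher on dm6 than on dm3, while the highest signal on the arms moved by 1.01 times, so a difference in how the builds were aligned may also contribute. All 3 of these explanations stay open. Leaving these regions out of the list of replicate 3 moved the mean share of thresholded peaks found in a replicate from 79.9% to 80.0%.

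On dm3, regions also lay on scaffolds outside the named arms, which no comparison used. There were 33 in replicate 1, 46 in replicate 2, 96 in replicate 3 and 6 in the pooled list, and 0 of them passed the threshold.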

How the results depend on the processing

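All alternatives were planned except 2 that were added after seeing the data, the 5'-most TSS of each gene and the replicate lists limited to chromosome arms. Over 86 values under alternatives for the 9 planned results, 67 counted as kept. Tested values had to keep their direction and side of the threshold, and replicate values to move by no more than the spread between replicates. Numbers of gene lists and of motifs had to stay within a fixed fold limit of the main number, whichever lists or motifs they held. The promoter excess (ratios of 2.90 to 6.15), the promoter signal difference in log2 units and in ranks, and the divergent excess (odds ratios of 3.63 to 4.79) kept their direction and side of the threshold under every alternative run. Replicate support was 75.3% with summits within 100 bp, 94.9% with lists of 2N regions, 99.7% with whole lists and 96.5% for the stronger 50% of peaks, values which longer lists or stronger peaks raise by construction. Sharing between replicate pairs was 58.9% with summits within 100 bp and 61.6% with 2N regions, and leaving out a replicate gave 64.0% to 72.2%. Likewise rho ran from 0.486 to 0.679, highest without replicate 3. The X ratio was 0.863 in replicate 3 alone, where it passed the threshold, and the cause was not tested. The number of gene lists above background fell from 2 to 1, leaving ribosomal proteins, with a 250 bp window, a background of genes with any region, the stronger 50% or the strongest 500 peaks, replicate 2 alone, the 5'-most TSS, and without each replicate (1 to 1). It was 3 in replicate 1 alone, where the Polycomb group (adjusted p = 0.00564, exact test) and trithorax group (0.0437) entered and Notch genes left (0.0518), and 3 in replicate 3 alone, where mitochondrial ribosomal proteins entered (0.00581) and Notch genes stayed (0.0353). With the strongest 500 peaks, 0 Notch genes had a peak, and the 3 lists below background fell to 0. The number of motifs above background fell from 7 to 1, DRE, with the strongest 500 peaks, where fewer windows were tested. Against shuffled windows 10 were above background, of which 4 are among the main 7, and between promoters with and without a peak 7, of which 3 are. GAGA, CAGCTG and TCT entered in both. Odds ratios turned below 1 for homeodomain (0.990) and GATA (0.959) sites against shuffled windows, which hold the same dinucleotides, and for TATA (0.537) and GATA (0.843) between promoters with and without a peak, where the cause was not tested. The X carried 15.7% of peaks on dm3 too, but its ratio to length was not run, for want of dm3 arm lengths here, and histone genes had no value against genes with any region. Depth is unknown, so its effect on weak regions could not be examined.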

Other observations

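The tests in this part were chosen after the results were seen. Grouping protein-coding genes by the letters that open their symbols gave 43 families of at least 15 genes, and 12 differed from background at an adjusted p under 0.05 by Fisher's exact test. Beyond ribosomal proteins, the PIG genes, which act in the synthesis and attachment of glycosylphosphatidylinositol anchors, had promoter peaks in 10 of 21 (47.6%, exact test, adjusted p = 0.000664), led by PIG-F (406.4), PIG-M (263.1) and PIG-G (230.8). The Pex genes of peroxisome assembly had them in 8 of 15 (53.3%, exact test, adjusted p = 0.00107), led by Pex11ab (686.2), Pex13 (214.8) and Pex10 (163.4), with Pex14 and Pex16 sharing 1 peak. The replicates' lists held 7, 10 and 10 PIG genes and 6 Pex genes each. Divergent promoters are common in both families (14 of 21 and 12 of 15), and draws with the same number of divergent promoters gave an expected 3.42 and 2.74 genes with a peak (permutation test, p = 0.0158 and 0.0325 after adjustment for the 43 families). Genes of the small subunit of the mitochondrial ribosome (mRpS) had peaks in 8 of 26 (exact test, adjusted p = 0.0269, but 0.394 in the same permutation test). Cytochrome P450 genes (Cyp) had peaks in 2 of 85 (exact test, adjusted p = 0.0135, but 0.138 by permutation). Ionotropic receptor genes (Ir), already part of the 179 receptor genes above, had them in 0 of 60 (exact test, adjusted p = 0.00447). A family of 24 genes whose symbols begin with pre had 10 with a peak, but all 10 belong to the mod(mdg4) locus and share 1 peak.

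Among the patterns weighed was the strength of the peaks at the tagged gene. Extra copies of the gene carried by the transgene would scale its signal alike along it. The strongest 5' region was 27.2 times as strong as the one in the coding span in the pooled list, which copies would leave unchanged, so whether they raised the rank of the peaks stays open. Weak pooled regions were frequent around the gene, with 13 within 10 kb, compared with a median of 3 for 10000 random protein-coding genes (percentile 99.9 per kb). The random genes were not chosen to have strong peaks, and only 11.6% of protein-coding genes had a promoter peak. This count thus cannot decide whether a broad rise over the locus adds to its signal. Binding of the protein to its own promoter is a hypothesis that remains, and neither the number of copies nor the line used for the control is given in the sources used here.

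Another pattern was a 7-mer. On 2L, 2R, X and 4, ACAGTGG (reverse complement CCACTGT) was the most enriched against dinucleotide-shuffled copies, in 121 of 1205 summit windows, compared with 1.16% of the copies. The arms 3L and 3R were left out of this 7-mer search, but not of the search of shorter words in the results above. There ACAGTG, a part of this 7-mer, was in 18.7% of summit windows against 8.32% of flanks. Values on these arms are thus not independent of that search. On 3L and 3R the 7-mer was in 7.16% against 1.74% of shuffled copies (odds ratio 4.35, exact p = 4.68e-18), which argues against base composition. Outside promoters it was in 43 of 430 of their summit windows against 2.09% of flanks (odds ratio 5.20, exact p = 2.34e-09), which argues against a sequence of promoters in general. At promoter summits of these arms the excess was smaller, with 31 of 604 against 3.01% of flanks (odds ratio 1.74, exact p = 0.0336). Compared with promoters of genes without a peak (2.02%), the odds ratio there was 2.63 (exact p = 2.09e-05). Of the 15 strongest peaks in the genome, 0 held it, compared with 27 of the 209 next strongest (exact p = 0.226). Some of these 15 share the interval at brwl. Across the thresholded list the 7-mer was in 58 of 447 windows of the strongest 20% and 34 of 447 of the weakest 20%. The odds ratio was 1.81 (exact p = 0.011), so it was not rarer at strong peaks as a set. Weaker pooled regions held it in 4.23%. The site was most frequent a little off the summits, with 76 sites within 50 bp and 151 between 50 and 100 bp (ratio 0.503, exact binomial p = 7.24e-07), compared with a mean of 35.4 per 50 bp beyond 250 bp. In the 579 peaks with a summit of every replicate within 25 bp the ratio was 0.5 (23 against 46 sites, exact binomial p = 0.00762). Both ratios go against the prediction for recognition at the summit, a ratio above 1. The 76 sites within 50 bp still exceeded the mean beyond 250 bp (exact binomial p = 5.06e-08). Ratios of 0.84 for DRE and 0.828 for Motif 1 did not differ from 0.503 by the test used (Fisher's exact test, p = 0.0545 and 0.114), which does not show that they are alike. Recognition of the site by the tagged protein at the summit thus stays open, as does binding beside it by this protein or another, which was not tested.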
